A study of Homo sapiens with 41 samples.

How the data were processed

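Peak lists of 32 samples of MDA-MB-231 cells were used, out of 41 samples in the series. The groups were taken from the sample labels: HDAC6 ChIP (control, inhibitor and shHDAC6, 2 each), HDAC6 CUT&Tag (control, 2), pan-acetyl ChIP (control and inhibitor, 2 each), PolII ChIP (control, inhibitor, shCtrl and shHDAC6, 2 each) and ATAC (the same 4 groups, 3 each). The submitters' processing notes name Trim Galore 0.6.7, Bowtie2 2.4.4, SAMtools 1.13, deepTools 3.5.1, MACS2 2.2.7.1 and ChIPseeker 1.28.2, without the role of each, and the build hg38. The peak lists are per sample and hold 9 columns for ChIP and CUT&Tag and 10 for ATAC, without a header. Their values were made by the authors: the fold of a peak over the caller's background is a deposited linear ratio, and the deposited −log10 of p and of q follow it. The deposited score is 10 times −log10 p in some lists and 10 times −log10 q in others, as a whole number. A peak's score and fold are the authors' own values and were used to rank or filter peaks within their own list, since ranks from lists of different lengths show no change. In ATAC lists they also served to recover background and pileup, which were compared between lists.

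Lists called on q with complete peak numbering stood beside lists called on p with gaps in the numbering, which shows removal of peaks after calling. Each same-numbered control and treated pair was called on the same measure, p or q, but the share of the numbering kept could differ. ATAC control lists 2 and 3 kept 3.92% and 3.90%, and inhibitor lists 2 and 3 kept 21.2% and 21.3%. HDAC6 ChIP replicate 2 kept 23.2% in control and 0.103% with the inhibitor. The HDAC6 ChIP replicates used different antibodies, CST in the first and Novus in the second, per the labels, and both knockdown lists used Novus. The peak names of the inhibitor Novus list carry a prefix that otherwise marks shCtrl lists, and those of a CUT&Tag control list carry a hairpin prefix; both were kept in the group their labels give. The labels do not say that replicates are separate cultures, so exact permutation p-values over lists measure only the spread between these samples, which may be technical. Fisher's exact tests take genes or regions as the unit and hold no spread between samples.

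Repeated lines at the same interval were merged, and chromosomes 1 to 22 and X were kept. Gene positions came from a RefSeq gene table of the same assembly that gives no strand. The promoter of each of 19974 protein-coding genes was therefore the gene end with a peak in more of the 32 lists, ± 1 kb. One end was chosen for 16725 genes and both were kept for 3249, of which 2611 had no peak at either end. Of 30 genes of known strand, 28 had the right end, 2 were tied and 0 were wrong. This does not extend to every called gene. For 18 protocadherin gamma genes called lost after knockdown, the end chosen was the far one that they share. A peak at an end shared by several genes counts for each of them. A planned analysis of 12 sequence motifs was not run, because a genome sequence was not used here. Presence needed an overlap of at least 1 bp. Regions were the merged peaks of all lists in a comparison.

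A promoter or region was lost when every control list and no treated list had a peak there, and gained in the reverse case. If a feature is marked in as many lists as a group holds, chance arrangement follows the groups with probability 0.1 in 3 against 3 and 0.333 in 2 against 2. Peak numbers and similarity of lists (Jaccard index of covered bases) were compared by exact permutation. Gene lists, HDAC6-bound promoters and shared changes were compared by Fisher's exact test, two-sided, against the genes or regions that could have changed. Benjamini-Hochberg adjustment was planned for gene lists, applied over 10 tests for bound promoters, and added over 4 tests for shared changes, where the unadjusted p is given beside it. There were 22 gene lists covering breast epithelial identity, stress and signalling, chromatin regulators, gene families and markers of leukocytes and neurons. They gave 204 tests and 9 calls at an adjusted p under 0.05. Lost members were also set against 10000 random lists matched on the decile of control percentile. Overlap of peaks was set against 100 random placements on the same chromosome.

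The groups, tests, gene lists and alternatives were fixed before the data were examined. So was the rule for named genes: HDAC6, then the 10 lost and 10 gained genes of highest mean within-list percentile, then up to 4 lost or gained members of each list. For HDAC6 occupancy the 15 highest promoters and up to 4 members of each called list were named, and for ATAC the 3 highest lost and gained distal regions. Some genes that the rule names are not reported here. Alternatives were a −log10 q of at least 5, equal list length (the strongest peaks of each list, as many as the shortest list holds), windows of 500 bp and 3 kb, an overlap of 200 bp, coverage of 50% of a region, all contigs, leaving out each list in turn and the replicate number as a block. Added after the data were seen were a common q floor (−log10 q of 1.3), either gene end, shared gene ends counted once, similarity among lists of other number only, backgrounds of accessible promoters, ATAC peaks at least 20 times above background and changes in opposite directions.

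ATAC background and summit pileup were recovered from the deposited fold and p. Same-numbered ATAC inhibitor and control lists deviated together from their group means (r = 0.553, 0.224 and 0.230 for the 3 numbers, across promoters, which are not independent replicates). The knockdown ATAC lists did not (−0.0134, −0.0299 and −0.0522). In both inhibitor groups list 1 was called on q and lists 2 and 3 on p, which alone can make all 3 values positive. The values thus set the first lists apart and cannot show how lists 2 and 3 pair. Prefixes in the peak names number lists 2 and 3 in opposite order in control and inhibitor. Pair ratios, sign flips and splits that part pairs take the replicate number as the pair.

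On simulated lists with 200 of 19974 genes changed, 100% of lost and of gained genes were recovered in each of the 6 comparisons. The treated lists were copies of control lists with planted changes, so this tests the calling logic and not noise. Between 29 and 51 other genes were called, all sharing a gene end with a planted gene except 1 of 46 in the ATAC inhibitor comparison. For PolII after knockdown, 2.2% of 500 random gene lists among 12485 genes fell below 0.05, and a planted odds ratio was recovered at 0.996 times its value. Pileup was recovered for 100% of 2000 simulated ATAC peaks. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.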

Results

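Chromatin was profiled in MDA-MB-231, a human triple-negative breast cancer cell line of epithelial origin, to compare cells with and without the HDAC6 inhibitor Nexturastat A (NextA) and cells with and without knockdown of HDAC6. HDAC6 is a deacetylase best known for acting on tubulin and other cytoplasmic proteins. Of 41 samples, 32 had a peak list, and the other 9 were not analysed here. The inhibitor was given at 5 µM for 2 days, and each library was made from 100000 cells. HDAC6 was mapped by ChIP in 2 control, 2 inhibitor and 2 knockdown samples and by CUT&Tag, an antibody-tethered tagmentation assay, in 2 control samples. Acetylated protein on chromatin (pan-acetyl antibody) was mapped in 2 control and 2 inhibitor samples. RNA polymerase II (PolII) was mapped in 2 samples each of control, inhibitor, control hairpin (shCtrl) and HDAC6 hairpin (shHDAC6) cells. Accessible chromatin was mapped by ATAC-seq in 3 samples of each of the same 4 groups. Lists held 235 to 63833 peaks for HDAC6 ChIP, 14458 and 22481 for CUT&Tag, 1418 to 61186 for pan-acetyl, 19519 to 31198 for PolII and 25878 to 79666 for ATAC. Read depth is not given in these lists, and a genome background was recovered only for ATAC. The absence of a peak therefore means that none was called, not that the signal was absent.

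A promoter was called lost when every control list and no treated list had a peak there, and gained in the opposite case. The strength of a named promoter is the percentile of the authors' fold within its own list, averaged over the lists that have the peak. Coordinates are those of the gene in GRCh38.

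**Figure D1:**
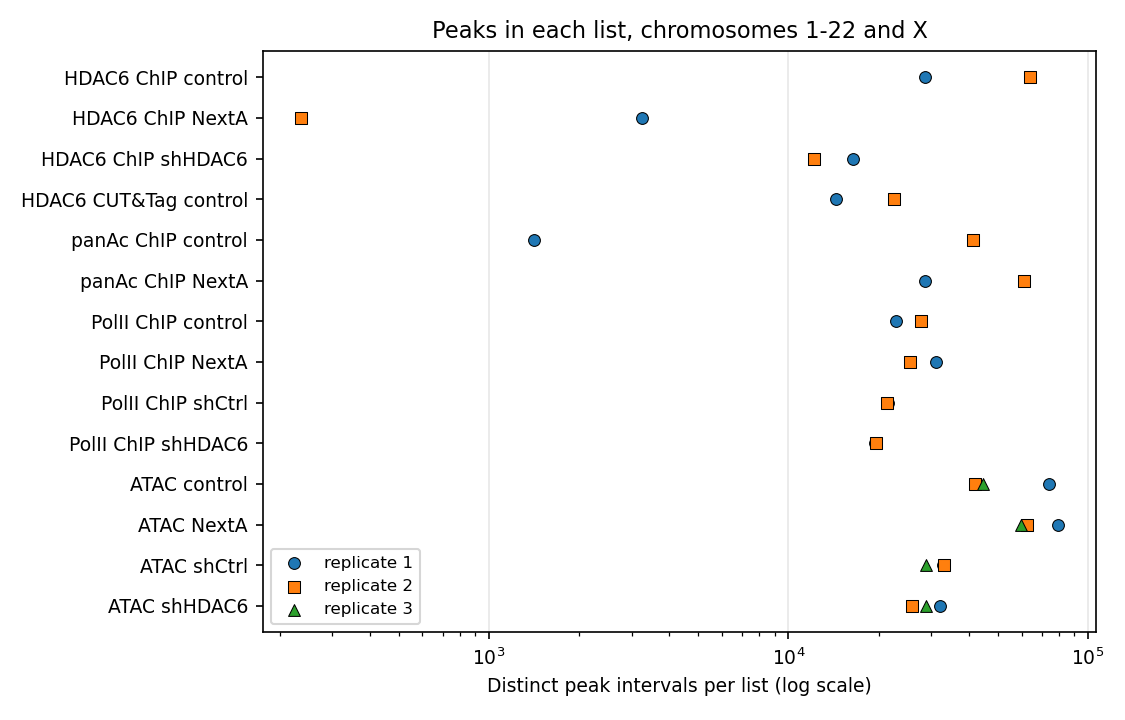
Number of peaks in each of the 32 lists (x axis, log scale), by assay and group, with 1 symbol per list and its shape giving the replicate number. HDAC6 ChIP fell from 28590 and 63833 peaks in control cells to 3256 and 235 with NextA, while the 8 PolII lists held 19519 to 31198.

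The first comparison asked where HDAC6 lies in control cells. HDAC6 marked 1627 promoters, 8.15% of 19974 protein-coding genes, in both ChIP and both CUT&Tag lists. CAMTA1 (chromosome 1, 6785454 to 7769706), a calmodulin-binding transcription activator, had the highest mean percentile, 97.4 over the 4 lists. ZNRF2 (96.3), the oxysterol-binding protein gene OSBP (95.7), PHTF2 and TMEM60 at a shared gene end (94.6), ZC3H6 (94.4) and COQ6 with FAM161B (94.2) followed. FBXO33 (93.9), TANC2 (93.7), RFX1 (93.3), METAP1D (93.0), BIRC2 (92.3), an inhibitor of apoptosis, DTNBP1 (91.4) and the ADP-dependent glucokinase gene ADPGK (91.4) completed the highest 15. Of the autophagy, lysosome and ubiquitin genes, 8 of 32 were bound (25.0%) against 8.12% of other genes, an odds ratio of 3.77 (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.0375 over 22 lists). They included ATG3, which conjugates lipid to ATG8 proteins (84.7), the lysosomal protease gene CTSL (75.6), LAMP1 (72.9) and the proteasome subunit gene PSMA1 (66.5). None of 390 olfactory receptor genes was bound (adjusted exact p = 1.2e-13). Among promoters accessible in all 3 control ATAC lists, neither list was called (autophagy: odds ratio 2.25, adjusted exact p = 0.678; olfactory receptors: 0 of 7, adjusted exact p = 0.990), whereas zinc finger ZNF genes were bound less often than other genes (26 of 349, odds ratio 0.456, adjusted exact p = 0.000672).

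Of the 1627 HDAC6-marked promoters, 93.2% had an ATAC peak in all 3 control lists, against 51.5% of all genes, and 95.8% had PolII in both control lists, against 55.0%. Peaks of the ChIP list made with the CST antibody overlapped these ATAC regions in 38.7% of cases, those of the Novus list in 4.69%, and those of the CUT&Tag lists in 65.5% and 49.3%. Random placements gave 1.304% to 1.55% (permutation test, one-sided, p = 0.0099 in each case, the smallest that 100 placements can give). The ChIP and CUT&Tag promoter sets shared 1627 genes where chance gives 1072, an odds ratio of 2.46. Within accessible promoters that odds ratio was 1.04 (Fisher's exact test, two-sided, p = 0.397).

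The next comparison asked how the inhibitor changed HDAC6 on chromatin. HDAC6 peaks were lost at 2754 promoters, 91.5% of the 3010 marked in both control lists, and none was gained. List length nearly fixes this outcome, because the inhibitor lists covered promoters of only 836 and 39 genes. At equal list length, 235 peaks in each list, 0 promoters were lost and 1 was gained. With the common q floor 88 were lost and 0 gained. The gene for the ubiquitin ligase WWP1 (chromosome 8, 86342547 to 86468503) had the highest control percentile among lost promoters, 97.5 (n = 2 lists). PHTF2 and TMEM60 (97.4), ZC3H6 (97.3), the shared end of APBB3, SLC35A4 and LOC131768270 (96.9), ANKRD36B (96.5), NFKB1 (96.4), which encodes a subunit of NF-kB, and COQ3 (96.0), a coenzyme Q synthesis gene, came next. Lost members of the fixed lists included the shared end of the antigen processing genes PSMB9 and TAP1 (94.9), ZNF609 (89.4), CCN1 (88.2), the acetyltransferase gene KAT6B (85.5), COX5B (83.7), the kinesin gene KIF5B (82.6), the cohesin regulator PDS5A (82.5), MCM6 (78.6), RPS29 (77.2), SNAP25 (75.6), TUBB2A (72.9) and CTSL (69.5). The promoter of HDAC6 itself (X chromosome, 48801398 to 48824982) had no HDAC6 ChIP peak in either group. With 91.5% of marked promoters lost, these lists were too small to be called lost more often: all 16 ribosomal protein promoters lost gives p = 0.390 (Fisher's exact test, unadjusted). None was called lost less often. All 16 ribosomal protein, all 9 deacetylase, acetyltransferase and reader, all 6 oxidative phosphorylation and all 8 tubulin, cilium and cytoskeleton promoters that HDAC6 marked were lost, as were 44 of 48 ZNF and 9 of 12 oncogene promoters.

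Peak numbers fell from 28590 to 3256 in the pair made with the CST antibody, a ratio of 0.114, and from 63833 to 235 in the Novus pair, a ratio of 0.00368. The peak names of the list labelled inhibitor in the Novus pair carry a prefix used for shCtrl lists. Its peak numbering reached 227815, against 275353 in the control Novus list, so most of this fall arose when peaks were removed after calling. The means were 46212 ± 24921 in control and 1746 ± 2136 with the inhibitor (SD, n = 2 each; exact permutation test, two-sided, p = 0.333, the smallest that 2 lists against 2 can give). The Jaccard index was 0.0210 within groups, where antibodies always differ, and 0.0163 between groups (exact permutation test, one-sided, p = 0.667). Between groups it was 0.00224 for different antibodies and 0.0304 for the same one. The 2 control lists shared 0.0402, but the 2 inhibitor lists shared 0.00181, less than lists of different groups and antibodies. With different antibodies alone, the higher within-group mean thus rests on the control lists (exact p = 0.5, the smallest that 2 splits can give). Recovery of control peaks in the CST pair rose with their fold, from 2.4204% of 14295 peaks below the median to 94.1% of 286 peaks in the top 1%. In the Novus pair it stayed low at every fold: 18 of 639 peaks in the top 1% were found again (2.82%), and 0.0274% to 0.0522% in the other groups. With only peaks at a −log10 q of 5 or more, the CST pair held 654 and 633 peaks and the Novus pair 26 and 1. No promoter was called lost, but 26 control peaks leave little that could be.

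**Figure D2:**
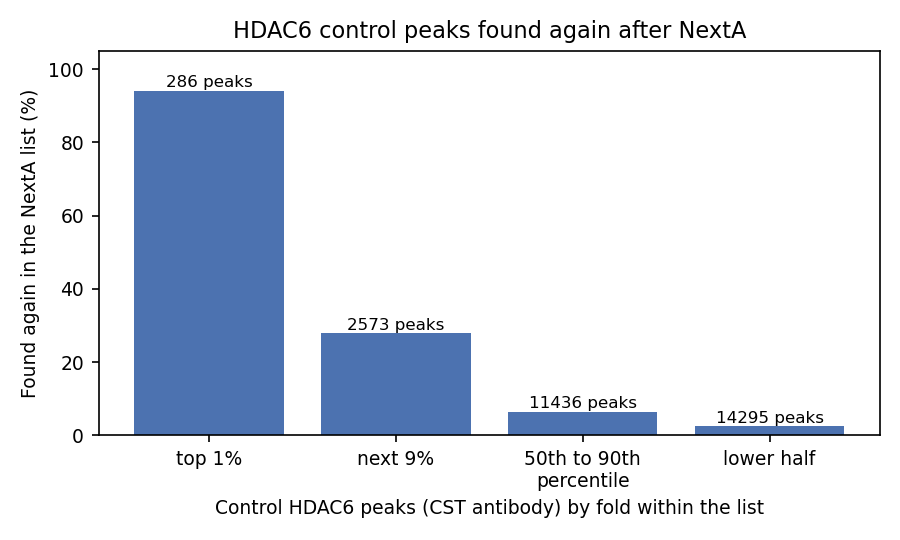
Percent of control HDAC6 ChIP peaks (CST antibody) that overlap a peak of the inhibitor list, by fold of the control peak within its list, with the number of peaks above each bar. The share was 94.1% in the top 1%, 27.8% in the next group, 6.39% in the third and 2.4204% below the median.

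HDAC6 ChIP after knockdown was set against the control list made with the same Novus antibody, since a control hairpin list of this antibody was not used here. The lists labelled shHDAC6 held 16441 and 12152 peaks and covered promoters of 573 and 387 genes, against 4514 genes in the control list. Of the 63833 control peaks, 0.732% and 0.752% were found again, where random placement gives 0.541% and 0.396%. The knockdown lists also shared little with each other: 0.511% of the first were found in the second, against 0.386% at random. With only peaks at a −log10 q of 5 or more, the control list held 26 peaks, of which a mean of 11.5% ± 16.3 (SD, n = 2 lists) was found again. No test between groups was made, because a single control list is available for this antibody here.

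Pan-acetyl ChIP asked whether the inhibitor changed acetylation on chromatin. Pan-acetyl peaks were gained at 3990 promoters, 25.8% of the 15448 without a peak in either control list, and no promoter was lost. The first control list held only 1418 peaks, which limits losses. At equal list length 42 promoters were lost and 106 gained. With the common q floor 0 were lost and 318 gained. CSNK1G3 (chromosome 5, 123512177 to 123617049), a casein kinase gene, had the highest percentile in the inhibitor lists, 99.5 (n = 2). WDR43 (99.4), the beta-catenin inhibitor gene CTNNBIP1 (99.4), the complex I subunit gene NDUFB10 (99.3), SYNGR4 with TMEM143 (99.3), PXK (99.2), HDGF with PRCC (99.1) and KRI1 (99.02) followed. The HDAC6 promoter had a pan-acetyl peak in 1 of 2 inhibitor lists and in neither control list.

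Gained promoters were more frequent in 6 of the fixed lists than among other genes (Fisher's exact test, two-sided, adjusted over 204 tests). Among deacetylase, acetyltransferase and reader genes 18 of 24 were gained (odds ratio 8.65, adjusted exact p = 4.4e-05), including the mitochondrial deacetylase gene SIRT3 (percentile 96.2), KAT2A (81.5), CHD4 (78.9) and HDAC8 (74.8). Among oncogenes and growth signalling genes 17 of 22 were gained (9.80, adjusted exact p = 4.4e-05), including NOTCH2 (93.4), MTOR (91.3) and HRAS (88.2). Heat shock and chaperone genes gained 12 of 17 (6.91, adjusted exact p = 0.00474), with HSPA8 (91.6), CCT3 (90.6), HSPH1 (90.3) and HSP90AA1 (84.7). Oxidative phosphorylation genes gained 15 of 23 (5.40, adjusted exact p = 0.00413), with COX7C (90.01) and ATP5F1B (88.3). Ribosomal protein genes gained 12 of 18 (5.76, adjusted exact p = 0.00815), with RPL22 (98.0), RPS28 (94.6) and RPS13 (91.0). Cell cycle genes gained 8 of 11 (7.67, adjusted exact p = 0.0339), with CDK4 (87.0), CDK2 (75.4), CDC20 (68.1) and CCNB1 (65.3). Olfactory receptors gained 1 of 370, OR2V2, against 26.5% of other genes (adjusted exact p = 9.6e-45).

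The other lists were not called. They included p53 and DNA damage genes (9 of 15, adjusted exact p = 0.0981; GADD45A 94.1, ATR 90.1), tubulin, cilium and cytoskeleton genes (9 of 16, 0.147; TTLL4 98.8, MAP4 89.4), hypoxia and glycolysis genes (8 of 16, 0.380; LDHA 86.3), CTCF, cohesin and chromatin architecture genes (6 of 11, 0.380; STAG2 78.9) and autophagy genes (9 of 22; PSMB5 93.7). AP-1 and YAP/TEAD targets gained 3 of 10, mesenchymal genes 4 of 20, epithelial and luminal genes 4 of 22 and basal breast genes 0 of 14. Interferon and antigen presentation genes gained 6 of 27 (B2M 95.5), NF-kB and cytokine genes 6 of 22, replication-dependent histone genes 16 of 60 and ZNF genes 112 of 402. Markers of other cell types gained 1 of 26 for leukocytes (CD68; adjusted exact p = 0.108) and 0 of 20 for neurons (adjusted exact p = 0.0775). When only promoters accessible in all 3 control ATAC lists were compared, none of the list calls remained: oncogenes gained 16 of 19 against 50.2% of other genes (odds ratio 5.30, adjusted exact p = 0.241).

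Peak numbers rose from 1418 to 28473 in the first pair and from 41411 to 61186 in the second, ratios of 20.1 and 1.48. The means were 21415 ± 28279 and 44830 ± 23132 (SD, n = 2 each; exact permutation test, two-sided, p = 0.667, where 0.333 is the smallest that can be reached). The Jaccard index was 0.0728 within and 0.0360 between groups (exact permutation test, one-sided, p = 0.333). At a −log10 q of 5 or more the pairs moved apart, from 15 to 3854 and from 202 to 75 peaks, and no promoter was called gained, which lists this short nearly fix. Without the first control list the balance of regions turned, to 36305 lost and 4940 gained, from 0 lost and 4364 gained with all lists, and 426 promoters were lost beside 4570 gained.

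PolII occupancy with the inhibitor differed from control at few promoters: 9 were lost and 68 gained, while 10754 had a peak in all 4 lists. ACSS2 (chromosome 20, 34874989 to 34927959), which makes acetyl-CoA from acetate, lost a peak of control percentile 65.4 (n = 2). The other lost promoters were LOC124904958 (69.9), ZNF486 (44.2), ZNF93 (42.1), ZNF737 (30.5), ZNF883 (25.6), BTN3A1 (21.4), the sodium leak channel gene NALCN (9.64) and CTTNBP2NL (8.32). The highest gained promoters were ANAPC5 (chromosome 12, 121308245 to 121354209; 86.2), a subunit of the anaphase-promoting complex, MAMDC4 (69.6), FOXH1 (68.6), the tumour suppressor gene RASSF1 (62.1), CORT (56.9), LOC122455342 (50.4), PDE6G (45.2), C8orf89 (44.7), ECHDC2 (43.5) and TFPI (43.3). CDKN1A, the cell cycle inhibitor p21, was the gained member of the p53 list (38.4; 1 of 2 members without control peaks, adjusted exact p = 0.254). ZNF genes were 4 of the 9 lost promoters, 4 of 351 against 5 of 10625 other genes, an odds ratio of 24.5 (Fisher's exact test, two-sided, adjusted p = 0.00465). Random lists matched on control percentile gave p = 0.0008 (permutation test). Both tests take genes as independent, but ZNF93, ZNF486 and ZNF737 lie close together on chromosome 19, between 19900946 and 20565781. The call thus rests on that stretch and ZNF883. Among accessible promoters the ZNF odds ratio was 21.7, with 3 of 318 lost and an adjusted p of 0.0995. HDAC6 had a PolII peak in all 4 lists, at percentile 61.0 in control and 65.5 with the inhibitor.

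PolII peak numbers went from 22926 to 31198 in the first pair and from 27786 to 25373 in the second (ratios 1.36 and 0.913; exact permutation test on the means, two-sided, p = 0.667, n = 2 each). Covered length rose in both pairs, from a mean of 30.8 ± 6.68 to 42.6 ± 7.37 Mb (SD, n = 2 each; exact p = 0.333, the smallest possible). The Jaccard index was 0.306 within and 0.408 between groups (exact permutation test, one-sided, p = 0.667). Between groups, same-numbered lists shared 0.517 and other-numbered lists 0.298. Among lists of other number the within-group index was thus slightly higher (exact p = 0.5, the smallest possible). Grouping them by number instead gave 2064 promoters that differed, against 77 for the treatment. The excess of gains turned at a −log10 q of 5 or more, to 31 promoters lost and 16 gained, and without the first control list, to 314 lost and 175 gained.

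For the knockdown, the targeted gene was looked at first: the HDAC6 promoter had a PolII peak in both shCtrl and both shHDAC6 lists, at percentiles 42.1 and 68.8. A hairpin acts on the transcript, and HDAC6 RNA and protein were not analysed here. PolII peaks were lost at 156 promoters and gained at 160, while 12225 had a peak in all 4 lists. With overlapping gene ends counted once, 132 were lost and 153 gained: 19 of the 156 are protocadherin gamma genes called through the same far end, at chromosome 5, 141512975. PCDHGC3 (lost) and PCDHGC4 (gained), of the same cluster, were called at their own starts. ZNF621 (chromosome 3, 40523106 to 40539782) was the highest lost promoter, at percentile 97.3 in shCtrl (n = 2), followed by the NAD kinase gene NADK (83.7), LIN28A (79.2), the ubiquitin ligase gene SIAH1 (75.3), ATN1 (62.2), CYREN (60.5), SDS (57.1), SPX (55.8), NDEL1 (51.7) and PCOLCE (51.5). The highest gained were LRRC27 (chromosome 10, 132330063 to 132381508; 74.4), the tubulin gene TUBB8 (64.1), AIG1 (62.3), CCZ1 (52.2), HSPA2 (46.1), EPC1 (45.5), TMC8 (45.3), ZNF230 (42.0), KCTD2 (40.4) and ZNF136 (40.1). Interferon genes lost 2 of 20, ISG20 (28.4) and MX1 (6.63), against 1.24% of other genes (adjusted exact p = 0.273), and gained IFIH1 (18.7). Single lost members of other lists were IL6 (22.2), ANGPTL4 (5.12) and the neuronal gene SNAP25 (39.1; 1 of 7, adjusted exact p = 0.709). Single gained members were CD44 (5.04) and TFEB, a transcription factor of lysosomal genes (19.9; adjusted exact p = 0.254). ZNF genes lost 3 of 367 and gained 5 of 132 (adjusted exact p = 1 for both). Olfactory receptors gained 0 of 386 (adjusted exact p = 0.00724), and this list had 3 members among accessible promoters, too few for a call (adjusted exact p = 1).

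PolII peak numbers were 21449 ± 172 in shCtrl and 19538 ± 26.2 in shHDAC6 (SD, n = 2 each), a ratio of 0.911, lower in both pairs (exact permutation test, two-sided, p = 0.333, the smallest possible). The share of peaks at promoters was 50.4% ± 0.328 and 55.5% ± 0.172. Lists of the same group shared 0.804 of their covered length (Jaccard index) and lists of different groups 0.678 (exact permutation test, one-sided, p = 0.333, n = 2 each). The other ways of grouping the 4 lists gave 17 and 21 promoters that differed. At a −log10 q of 5 or more the direction of the peak number turned, with a ratio of 1.08, and gains outnumbered losses, with 81 promoters lost and 567 gained. With all peaks, regions were lost more often than gained (1996 and 842), and this turned to 196 and 879.

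**Figure D3:**
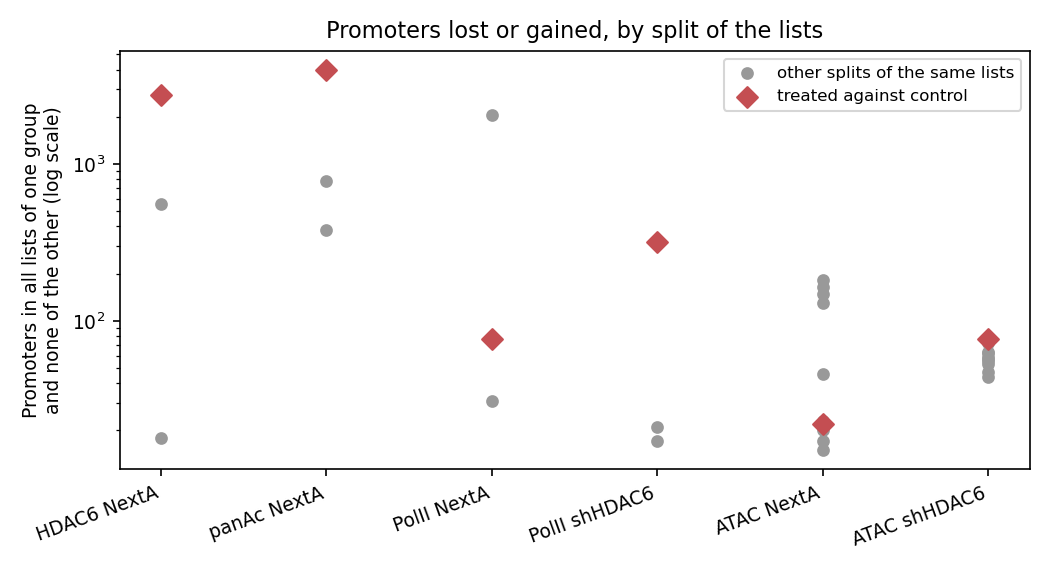
Number of promoters with a peak in every list of one group and in no list of the other, for the real groups and for each other way of grouping the same lists, by comparison (y axis, log scale). The real grouping, drawn as diamonds, gave 316 in PolII after knockdown against 17 and 21, and 77 in PolII with the inhibitor against 2064 and 31.

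Chromatin accessibility with the inhibitor was compared next. ATAC peaks were lost at 8 promoters and gained at 14, while 9620 had a peak in all 6 lists. FGF1 (chromosome 5, 142592178 to 142698070), a fibroblast growth factor gene, was the highest gained promoter, at percentile 85.3 (n = 3). CYP4F12 (53.8), the retinoic acid receptor gene RARA (49.3), SERPINB12 (47.7), HMGCLL1 (37.6), DPF1 (36.0), TECTB (30.9), NCALD (22.9), PSG7 (19.3) and SULT1A2 (17.0) followed. The lost promoters were the acetylcholine receptor subunit gene CHRNB2 (36.0), ZNF577 (33.4), RBPMS (30.1), BIN3 (28.3), SUSD4 (27.3), KLHL29 (20.7), TRAF3 (16.2) and ETNK2 (13.6). A promoter marked in exactly 3 of 6 lists follows the groups in 10% of arrangements by chance. No gene list was called. Among all regions 632 were gained and 76 lost, and 2.69% of the gained regions lay at a gene end against 23.7% of the lost and 39.6% of those in every list. The highest gained distal regions were 7323 bp from SLC35B4 (chromosome 7, 134327661 to 134328420; 78.8), inside KCND2 (chromosome 7, 120733171 to 120733751; 78.4) and 129492 bp from ARPP21 (chromosome 3, 35923978 to 35924595; 77.1). The highest lost were 13932 bp from TENT5B (chromosome 1, 27026782 to 27027899; 62.4), inside SCP2 (chromosome 1, 52946761 to 52947333; 56.8) and inside GSE1 (chromosome 16, 85253003 to 85253718; 55.1).

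ATAC peak numbers were 53528 ± 17783 in control and 67369 ± 10756 with the inhibitor (SD, n = 3 each), higher in 3 of 3 pairs with ratios of 1.08, 1.49 and 1.34 (exact permutation test, two-sided, p = 0.3, where 0.1 is the smallest possible; 0.25 by sign flips within pairs, also the smallest). Covered length rose from 33.2 ± 1.66 to 38.9 ± 3.07 Mb (exact p = 0.1). The Jaccard index was 0.371 within and 0.397 between groups (exact permutation test, one-sided, p = 0.5). Between groups it was 0.497 for same-numbered lists and 0.348 for the others. Against the latter the within-group index was higher (exact p = 0.25 over the 4 splits that part every same-numbered pair, the smallest possible). Among peaks with a summit at least 20 times the genome background the mean ratio over the pairs was 0.965. At equal list length the balance turned, to 36 promoters lost and 5 gained and 186 regions lost and 150 gained. The HDAC6 promoter was accessible in all 6 lists (84.6 and 83.6).

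**Figure D4:**
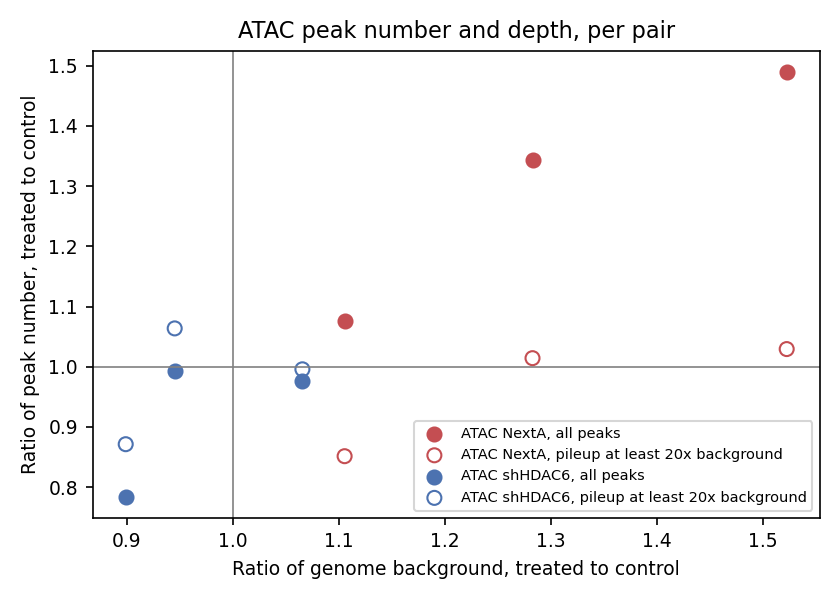
Ratio of peak number (y axis) against ratio of genome background (x axis), treated to control, for each same-numbered ATAC pair, with filled symbols for all peaks and open symbols for peaks at least 20 times above background. The mean ratios of background, all peaks and high peaks were 1.303, 1.303 and 0.965 in the inhibitor pairs, and 0.970, 0.918 and 0.977 in the knockdown pairs.

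After knockdown, the HDAC6 promoter was accessible in all 6 ATAC lists, at percentile 97.4 in shCtrl and 90.6 in shHDAC6. Accessibility was lost at 38 promoters and gained at 38, while 9339 had a peak in all 6 lists. The balance depended on the peaks and lists used: 31 were lost and 82 gained at equal list length, 31 and 55 at a −log10 q of 5 or more, and from 120 and 58 to 72 and 112 with 1 list left out. OR7E24 (chromosome 19, 9206488 to 9252625; 64.2, n = 3), FGF1 (58.3), the shared end of C11orf97 and the DNA repair gene MRE11 (47.3), the kinesin gene KIF13B (46.3), SLC9C1 (40.9), C4orf51 (39.2), MUC8 (38.6), SLC16A14 (38.1) and CDH12 (36.9) were the highest lost. DHX32 (chromosome 10, 125836337 to 125896485; 63.0) with FANK1 at the same gene end, ZNF709 (47.6), the mitochondrial poly(A) polymerase gene MTPAP (46.7), SRSF12 (46.2), LOC107987432 (36.9), SLC14A1 (34.7), SLA2 (33.3) and VPS37B (33.3) were among the highest gained. Members of the fixed lists were DCTN1, a dynactin subunit gene (lost, 33.9), IER2 (lost, 2.45) and RPL38 (gained, 0.709; 1 of 2 ribosomal genes without shCtrl peaks, adjusted exact p = 0.150). The single lost olfactory receptor was 1 of 6 (adjusted exact p = 0.254). A promoter marked in 3 of 6 lists again follows the groups in 10% of arrangements by chance. Distal regions lost lay inside GRIN3A (chromosome 9, 101704942 to 101705717; 80.9), KALRN (chromosome 3, 124550073 to 124551207; 72.6) and LAMA2 (chromosome 6, 129318291 to 129319036; 72.1). Distal regions gained lay 18361 bp from MRPL19 (chromosome 2, 75627837 to 75628422; 69.0), inside STAU2 (chromosome 8, 73665351 to 73665832; 63.9) and inside PPT1 (chromosome 1, 40078527 to 40079223; 63.4). In all, 521 regions were lost and 186 gained.

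ATAC peak numbers were 31586 ± 2342 in shCtrl and 28889 ± 3122 in shHDAC6 (SD, n = 3 each), a ratio of 0.915, lower in 3 of 3 pairs (0.977, 0.784 and 0.993; exact permutation test, two-sided, p = 0.2, where 0.1 is the smallest possible). At a −log10 q of 5 or more the ratios were 1.09, 0.785 and 1.003, higher in 2 of 3 pairs. These lists showed no pairing by number, so the ratios of single pairs and their counts depend on the numbering. Lists of the same group were slightly more alike than lists of different groups (Jaccard index 0.518 and 0.505; exact permutation test, one-sided, p = 0.1, the smallest possible, n = 3 each).

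Promoters bound by HDAC6 in both control ChIP lists were then compared with all others. Most of them rest on Novus peaks below the common q floor, which 179 of 63833 peaks of that list reached. Pan-acetyl peaks were gained at 762 of 1561 bound promoters (48.8%) and 23.2% of the others, an odds ratio of 3.15 (Fisher's exact test, two-sided, adjusted p = 7.7e-94 over 10 tests). After knockdown, PolII was lost at 3 of 2903 bound promoters and 153 of 9582 others (0.0638, adjusted exact p = 1.2e-13), and gained at 22 of 95 bound and 138 of 7158 others (15.3, adjusted exact p = 2.2e-16). Binding was defined in control cells and not in shCtrl cells. Bound promoters without a PolII peak numbered 95 in both shCtrl lists but 23 in both control lists. Most of the 95 thus had a PolII peak in at least 1 control list, and a gain may be a peak not called in shCtrl. ATAC peaks were gained after knockdown at 13 of 226 bound and 25 of 7116 others (17.3, adjusted exact p = 1.1e-10), and lost at 5 of 2275 bound and 33 of 7786 others (0.517, adjusted exact p = 0.402). With the inhibitor, bound promoters held 0 of the 9 lost and 68 gained PolII promoters and 2 of the 8 lost and 0 of the 14 gained ATAC promoters (adjusted exact p = 0.253, 1, 1 and 1). The absence among gained promoters depended on single lists. Without each control list in turn the odds ratio of ATAC gained was 5.91, 7.06 and 6.09 (unadjusted exact p = 3.4e-07, 0.00142 and 0.000367), and without each inhibitor list 1.99, 1.03 and 1.77; that of PolII gained was 4.68 without the second control list (unadjusted exact p = 2.7e-18). With overlapping gene ends counted once, the odds ratios after knockdown were 0.0730 for PolII lost, 14.9 for PolII gained and 15.8 for ATAC gained. Other alternatives with all lists kept gave 7.46 to 57.2 for PolII gained, 9.06 to 61.3 for ATAC gained and 2.91 to 8.28 for pan-acetyl gained, the 2 values above 50 for promoters bound in all 4 HDAC6 lists. Among accessible promoters alone, the odds ratios were 1.296 for pan-acetyl (adjusted exact p = 0.000569), 4.94 for PolII gained (0.000923), 3.88 for ATAC gained (0.00207) and 0.148 for PolII lost, which was no longer called (0.0655).

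Inhibitor and knockdown changes were finally set against each other. ATAC regions gained in both numbered 3, where independent lists give 0.786, an odds ratio of 3.97 (Fisher's exact test, two-sided, unadjusted p = 0.0443; adjusted over 4 tests 0.110). At equal list length it was 1.0, and with 50% of the region covered 1.04. These lie between genes at chromosome 11, 120172085 to 120172795, chromosome 18, 28961529 to 28962273, and the X chromosome, 130192122 to 130193022, and were named after their values were seen. Regions changed alike in either direction numbered the same 3, and 46 of 100 groupings of the lists, the real one included, gave as many, up to 17. No ATAC region was lost in both, where 0.151 is given by independent lists. PolII regions gained in both numbered 11, at SKI, TESK2, TCF25, FAM168B, TOP3B, TRMU, NR2C2 with MRPS25, INTS1, EIF3B, FUBP3 and a place between genes on chromosome 14, where independent lists give 6.001 (odds ratio 1.90, unadjusted exact p = 0.0552, adjusted 0.110). This depended on single lists: the odds ratio turned to 0.02001 without the second inhibitor list (unadjusted exact p = 1.1e-173), and was 2.85 without the first (4.0e-17), 3.63 without the second control list (9.5e-12) and 2.22 with 50% of the region covered (0.00452).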

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

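The count of ATAC peaks at 20 times the background was added after the data were seen; the tests of nonspecific peaks and of deeper libraries were set before their results.

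Mean ATAC peak numbers moved in opposite directions with inhibitor and knockdown: the log2 ratio of treated to control peaks was 0.37 on average with the inhibitor (0.11 to 0.57 over 3 pairs) and -0.13 with knockdown (-0.35 to -0.01 over 3 pairs), a difference of 0.50 (exact permutation test, two-sided, p = 0.1, the smallest 3 pairs against 3 can give). The means do not depend on how lists are paired, but the ranges and this p do. The knockdown lists showed no pairing by number: shHDAC6 list 1 held 32111 peaks and shCtrl list 3 held 28883. The p therefore rests on an arbitrary numbering. Deeper inhibitor libraries are a candidate explanation: the recovered genome background rose 1.303 times, as the peak number did, and peaks at least 20 times above it had a mean ratio of 0.965. Peaks found only in the inhibitor list lay at gene ends or control pan-acetyl or PolII peaks 3.005 times as often as random placements. This argues against all of them being nonspecific. Only 15.1% to 16.8% of them lay there, against 35.9% to 55.2% of peaks shared by both lists (6.16 to 8.03 times random). A share of nonspecific peaks among them therefore stays open, because a mixture would also exceed random placement. The biological explanation, a change of accessibility by the inhibitor, stays open beside depth and nonspecific peaks.

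In the HDAC6 ChIP list with inhibitor and CST antibody, 5.84% of lines lay off chromosomes 1 to 22 and X, against 0.870% in its control list. The unplaced or alternate contigs held 183 lines against 233, and 162 of the 183 overlapped control lines.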

How the results depend on the processing

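Promoters bound in all 4 HDAC6 lists and the settings listed above as added were chosen after the data were seen. Over 39 results and 177 alternative values without leaving out a list, 130 kept direction and call or stayed within 1.5 times. For 262 named genes, 1121 of 1834 values were the same, 713 moved and 0 reversed. Except where a construction is named, the cause was not tested. Read depth is unknown, so a missing peak is not evidence of missing signal, and weak peaks limit every count.

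At a −log10 q of 5 or more, HDAC6 and pan-acetyl changes with the inhibitor were 0 promoters and regions, in lists of as few as 1 and 15 peaks. PolII with the inhibitor gave 47 promoters (31 lost, 16 gained) and 81 regions (52 and 29), more lost than gained, with a peak ratio of 0.943. PolII after knockdown gave 648 promoters (81 lost, 567 gained) and 1075 regions (196 and 879), more gained than lost, with a peak ratio of 1.08. ATAC with the inhibitor gave 42 and 465, and ATAC after knockdown 86 promoters (31 lost, 55 gained) and 355 regions. HDAC6 occupancy was 0 promoters, and 11.5% ± 16.3 (SD of 2 lists) of only 26 control peaks were found again after knockdown, against 0.742% ± 0.0144 of all. At equal list length, HDAC6 changes were 1 promoter and 1 region, both gained, with within minus between similarity of -0.166, pan-acetyl 148 and 133 with -0.0312, PolII with the inhibitor 338 regions, ATAC with the inhibitor 41 promoters (36 lost, 5 gained) and 336 regions (186 and 150), which turns the excess of gains, PolII after knockdown 109 promoters lost and 215 gained, ATAC after knockdown 31 and 82, gene list calls 1, and the shared ATAC gained odds ratio 1.0. With the common q floor, HDAC6 changes were 88 and 80, pan-acetyl 318 and 322, PolII regions 358 with the inhibitor and 1344 (699 lost, 645 gained) after knockdown, with 108 promoters lost and 264 gained there. With coverage of 50% of the region or peak, HDAC6 regions were 1888, found again after knockdown 0.345%, shared ATAC gained 1.04 and shared PolII gained 2.22. ATAC peaks 20 times above background had a pooled ratio of 0.961. Against accessible promoters, gene list calls were 0, occupancy calls 1 and the odds ratio of PolII lost at bound promoters 0.148. Occupancy was 3010 promoters by ChIP alone and 7114 by CUT&Tag alone, by construction. With both control ChIP libraries 0.862% of peaks were found again after knockdown. For promoters bound in both CUT&Tag lists the odds ratio of ATAC lost after knockdown was 0.0575, and with 3 kb windows that of ATAC gained with the inhibitor was 2.92. Some odds ratios at bound promoters kept their call but moved. After knockdown, PolII gained went from 15.3 to 7.46 with 3 kb windows and 57.2 for promoters bound in all 4 HDAC6 lists (5 gained), and ATAC gained from 17.3 to 9.06 at equal list length and 61.3 for all 4 lists (4 gained). Pan-acetyl gained went from 3.15 to 8.28 for both CUT&Tag lists. Among lists of other number only, within minus between similarity turned from -0.101 to 0.00808 for PolII and from -0.0264 to 0.0233 for ATAC with the inhibitor.

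Leaving out each list in turn relaxes the rule that every list must carry or lack the peak, so counts rise by construction. HDAC6 promoters ranged from 2811 (without inhibitor replicate 2) to 9891 (without control replicate 2), and regions from 3780 (without inhibitor replicate 1) to 63433 (without control replicate 1). Pan-acetyl promoters ranged from 4802 (without inhibitor replicate 1) to 8029 (without inhibitor replicate 2) and regions from 6376 (without control replicate 2) to 56553 (without inhibitor replicate 1); without control replicate 1 they were 41245, of which 36305 lost and 4940 gained, and without inhibitor replicate 2 23817. PolII with the inhibitor rose in all 4 cases, to 309 to 489 promoters, the highest without control replicate 1, and 4445 to 12554 regions, the highest without inhibitor replicate 2. Losses outnumbered gains without control replicate 1 (314 and 175 promoters, 6804 and 1189 regions) and, for regions, without control replicate 2 (2977 and 1468). PolII regions after knockdown ranged from 4024 (without shHDAC6 replicate 2) to 4525 (without shCtrl replicate 1). ATAC with the inhibitor ranged from 49 (without control replicate 2) to 237 (without inhibitor replicate 1) promoters and from 1257 to 7583 regions for the same libraries. ATAC after knockdown ranged from 147 (without shHDAC6 replicate 3) to 184 (without shCtrl replicate 2) promoters and from 1390 (without shHDAC6 replicate 3) to 1810 (without shCtrl replicate 3) regions. Lost and gained promoters there, equal with all lists, were 120 and 58 without shHDAC6 replicate 1, 103 and 65 without shCtrl replicate 3, 72 and 112 without shCtrl replicate 2 and 66 and 95 without shHDAC6 replicate 2. Occupancy was 1705 to 6415, the highest without ChIP control replicate 2. Odds ratios at bound promoters ranged from 0 to 4.68 for PolII gained and 1.03 to 7.06 for ATAC gained with the inhibitor, and 0.409 to 0.8995 for ATAC lost after knockdown. Shared odds ratios were 0 to 7.37 for ATAC lost, 1.76 to 4.69 for ATAC gained and 0.02001 to 3.63 for PolII gained, the lowest without PolII inhibitor replicate 2. Other results kept direction and call, but some moved by over 1.5 times. The HDAC6 peak ratio of 0.0378 was 0.00509 without inhibitor replicate 1, 0.0705 without inhibitor replicate 2 and 0.0611 without control replicate 2. The pan-acetyl peak ratio of 2.09 was 1.083 without control replicate 1, 31.6 without control replicate 2 and 1.33 without inhibitor replicate 2. The odds ratio of pan-acetyl gained at bound promoters rose from 3.15 to 6.87 without inhibitor replicate 2, and that of ATAC gained after knockdown fell from 17.3 to 8.70, 9.11 and 11.5 without shCtrl replicates 3, 2 and 1.

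With the replicate block, the geometric mean ratios of peak number in same-numbered pairs were 0.0205 (HDAC6), 5.45 (pan-acetyl), 1.12 and 0.911 (PolII), 1.29 and 0.913 (ATAC), and the direction was kept. For lost and gained promoters the block is the same rule as the one used, so it tests nothing and is not counted. Pairs of 2 share a number (r = 0.0985 for pan-acetyl, 0.601 and -0.0202 for PolII with inhibitor and knockdown). HDAC6 pairs share the antibody (0.0600). ATAC after knockdown showed no pairing. The stratified odds ratio over control percentile gave no value for gained promoters, which have no control percentile, and the motif analysis was not run.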

Other observations

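Tests of a mislabelled list, of the calling rule, of copy number, of the ATAC promoter splits and of the shared ATAC changes in splits that part the pairs, and the comparisons of opposite directions and of pairs of assays, were chosen after the results were seen.

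FGF1 was accessible in all 3 inhibitor and no control ATAC lists (percentile 85.3), and in all 3 shCtrl and no shHDAC6 lists (58.3). ATAC regions gained with the inhibitor and lost after knockdown numbered 3: inside TGFBR2 (chromosome 3, 30693157 to 30694013), and between genes at chromosome 17, 30336389 to 30337181, and chromosome 2, 240060332 to 240061692, named after their values were seen. Their odds ratio was 0.451 (Fisher's exact test, two-sided, p = 0.254). For PolII 85 regions did so, less often than other regions (odds ratio 0.370, exact p = 1.4e-11), including UBE2J2, SESN2 and YBX1, chosen after their values were seen. Both pan-acetyl and PolII peaks were gained with the inhibitor at ANAPC5 and APOL6 (odds ratio 17.8, exact p = 0.00792, adjusted over 8 such tests 0.0634). LENEP lost both PolII and ATAC peaks after knockdown (odds ratio 16.6, exact p = 0.0630, adjusted 0.252). APOL6 and LENEP were named after their values were seen.

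Fewer HDAC6 peaks with the inhibitor were weighed first. In the CST pair (ratio 0.114) different calling rules are argued against, because the floors of the CST lists lay 0.00224 apart in −log10 q. Weak control peaks falling below the threshold are a candidate explanation there, with 94.1% of the top 1% found again and 2.4204% below the median. In the Novus pair (ratio 0.00368), where 2.82% of the top 1% was found again, a wrong sample stays open: 13.2% of the 235 peaks were found in the second shHDAC6 list (32.6 times random) and 0.426% in the first, against 16.2% in the control Novus list (7.45 times random), and no HDAC6 list of the shCtrl line was analysed here. Removal of peaks after calling kept 0.103% of the numbering in the inhibitor Novus list against 23.2% in the control Novus list. The highest peak numbers were 227815 and 275353, and the floors in −log10 p were 2.00084 and 2.00001. These values argue against a matching fall in the number of peaks called. The fall in this pair arose mostly at the removal, and what that was based on is not known. A loss of HDAC6 from chromatin through the inhibitor stays open, in the Novus pair only as far as the removal reflects it.

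PolII promoters lost and gained after knockdown were weighed next. Promoters near the detection floor are a candidate explanation, because the median percentile of lost promoters in the shCtrl lists was 16.8 against 69.5 for kept promoters. Gained promoters had a median percentile of 12.7 in the shHDAC6 lists. Copy number differences between the lines stay open: adjacent promoters changed in the same direction 1.73 times as often as in random sets (5 against 2.89, permutation test, one-sided, p = 0.17), and no chromosome stood out (lowest adjusted p = 0.623). That test was redone after its first form counted each gene and gave 10.9, since the shared end of 19 lost protocadherin gamma genes at chromosome 5, 141512975, had been counted for each. An effect of the knockdown itself stays open.

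For ATAC with the inhibitor 7 of 10 splits of the 6 lists gave at least as many promoters as the real 22, with a highest other value of 183, and 5 of 10 gave at least as many regions as the real 708, with 2832; 10 splits are too few for a share under 0.05. The splits with the highest values put the first control and inhibitor lists together, a structure that sets the first lists apart. Among the 4 splits that part every same-numbered pair, the real one had the most regions (708 against 224 to 427) and not the most promoters (22 against 15 to 46). After knockdown 1 of 10 splits, the real one, gave as many promoters (76 against at most 72) and 1 of 10 as many regions (707 against at most 560), again with too few splits for such a share. For ATAC regions changed alike in both experiments 46 of 100 splits, drawn without regard to the pairs, gave at least the real 3, up to 17. Among the 79 splits that part every inhibitor pair 17 did, up to 8, so chance cannot be excluded.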
